A study of Arabidopsis thaliana with 24 samples.

How the data were processed

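RNA from leaves of Arabidopsis thaliana was measured on 24 one-colour Agilent arrays, which give the abundance of each transcript as the brightness of the probes it binds. Per the labels' protocols, plants of 6 to 8 weeks were grown with a 12 h day at 125 µmol m⁻² s⁻¹, 22 °C by day and 16 °C by night, and 60% humidity. ABA, abscisic acid, is the hormone that closes stomata in drought. It was sprayed at 50 µM (25 µM of the active form) in 0.01% Triton X-100, and leaves were taken after 4 h. For control plants the labels record no spray. Effects of ABA thus cannot be told apart from those of the spray, the Triton X-100 or the 4 h. The label reaction started from 0.5 µg of RNA. The groups come from the sample labels: Col-0 (the wild type), the gad2 mutant and the gad1/2/4/5 quadruple mutant, each with and without ABA, with 4 arrays per group. The labels do not say that the 4 samples of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

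The authors' deposited scanner files hold linear intensity values per spot. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, which subtracts background within an array and does not scale arrays to each other. The intensity used here was the processed signal. The deposited files have no mean signal, so the background alternative used the spot's median intensity and the local background's median. The submitters' processing notes name limma, with no version and no model. The authors' deposited matrix gives log2 values per locus for the same 24 arrays. Its array medians lie between 7.66 and 7.70, so it had been brought to a common scale, by a method not given in the sources used here. The authors' deposited table of comparisons gives a signed linear fold where the adjusted p-value passed the authors' threshold, as wild type over mutant, gad2 over gad1/2/4/5, or ABA over control. The authors' deposited table marks the name of the gad2 line with an asterisk, which the sources used here do not explain. Fold changes here are mutant over wild type, gad1/2/4/5 over gad2, and ABA over control.

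Each array had 45220 spots, of which 43803 were not controls. Those carried 43603 distinct probes. Spots marked as non-uniform or as population outliers by the scanner software were left out, which removed 749 probe values over all arrays. Saturated spots would have been kept, but 0 probes were saturated. The values were log2 of the processed signal minus the array's 75th percentile, and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 31022 probes. Probes were named through the accession on the array, without version, and NCBI's gene table for assembly TAIR10.1. This matched 34348 probes to 25410 loci, of which 18464 had 1 probe and 6946 had more, and left 9255 probes with no locus. The array's grid was built on TAIR10, another release, so the table served only for names and for which genes neighbour each other. A gene's value was that of its kept probe with the highest mean, which gave 19246 genes. Among 5906 genes with several kept probes, probes were called in opposite directions for 1 gene in Col-0, 2 in gad2 and 1 in gad1/2/4/5 after ABA.

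Depth on an array is signal over background. The 75th percentile of the processed signal ran from 683 to 2250 between arrays, and 63.9% to 72.6% of probes were well above background. The number of arrays limits the precision. A gene not well above background on any array of a group has only a bound there. Its difference is then given as at least N-fold, from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. This bound holds only on the scale of the processed signal. Some of the authors' deposited folds, on the authors' own scale, are smaller than the bounds given here.

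Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 group means over all 24 arrays and 18 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 19246 genes. Errors of log2 fold changes are limma's standard errors. The comparisons were ABA against control in each genotype, each mutant against Col-0 without and with ABA, gad1/2/4/5 against gad2 without ABA, and the difference of each mutant's ABA response from that of Col-0. The test of shifts in gene lists was camera with a preset correlation between genes of 0.01, adjusted over the lists tested. It was repeated with a correlation estimated from the arrays, and fry was a further tool. The 23 lists held 350 members, of which 322 were tested. A list of root markers had a single member tested and was given no test.

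The groups, comparisons, gene lists, tests and most alternatives were chosen before the data were examined, and so was the rule for the genes named. It takes, per comparison, the 10 largest rises and 10 largest falls among called genes that have a symbol and whose groups do not overlap, up to 4 called members of each list, and all 5 GAD genes. The alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' matrix, no filter on dim probes, a filter asking for signal on all 24 arrays, the mean of a gene's probes, slide as a random or fixed block, scan day as a block, the replicate number as a block, array weights, fits on only the groups compared, a log2 fold change of at least 1, an adjusted p under 0.01, and leaving out each array in turn. For the lists, the authors' matrix, both fixed blocks and the left-out arrays were added after the data were seen.

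The arrays came from 14 slides with up to 4 array positions each, read on 4 scan days. All 4 arrays of ABA-treated gad1/2/4/5 sat on a slide of their own, read on a day of its own, so for that group slide, day and treatment cannot be told apart. The other 5 groups were spread over the remaining 3 days. Fits with a fixed block used those 20 arrays, and slide as a fixed block left only 3 residual degrees of freedom against 13 with scan day.

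The fit was tested on simulated data with 19246 genes. For gad2 against Col-0 without ABA it recovered 32% of genes changed by 1.5-fold, 62% at 2-fold, 96% at 4-fold and 98% at 8-fold, and 8 of 152 genes called had not been changed. For the difference in ABA response of gad1/2/4/5 the shares were 8%, 48%, 80% and 88%, and 3 of 115 calls had not been changed. A list shifted by 0.5 on the log2 scale had an adjusted p of 7.2e-12 by camera, and 0 of the other lists were called. Each gene was simulated independently, so this could not show false list calls that arise from correlation between genes. Tables were read with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 under Python 3.11.15. Probes with no locus were tested by themselves and used in no comparison of genes.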

Results

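Transcript levels were measured in leaves of wild-type Arabidopsis (Col-0), of a mutant of GAD2 and of a quadruple mutant of GAD1, GAD2, GAD4 and GAD5. Leaves came from control plants and from plants 4 h after a spray with ABA. For control plants the labels record no spray, so changes put down to ABA below include any effect of the spray itself. GAD genes encode glutamate decarboxylase, the enzyme that makes GABA from glutamate, and the study asks how GABA bears on stomatal signalling. Each of the 6 groups had 4 arrays, and each of the 24 arrays read 43603 probes. The share of probes well above background ran from 63.9% to 72.6%. Replicates of a group correlated across genes with r between 0.968 and 0.993, and genes are not independent replicates. The median SD of a gene within a group was 0.25 on the log2 scale. The first principal component, 40.3% of the variance, set all ABA arrays (at or above 23.5) apart from all control arrays (at or below -22.3). Log2 fold changes below carry limma's standard error, with n = 4 arrays per group.

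The mutated genes were read first. GAD2 (AT1G65960) had a log2 signal of 4.78 ± 0.13 (SD, n = 4) in control Col-0 and 0.87 ± 0.14 in control gad2, a limma log2 fold change of -3.91 ± 0.21 (adjusted p = 1.15e-10). In control gad1/2/4/5 it lay at 1.22 ± 0.08, a change of -3.56 ± 0.21 (limma, adjusted p = 5.49e-10). GAD2 stayed well above background on all arrays of both mutants. GAD1 (AT5G17330), at the probe used for it, and GAD4 (AT2G02010) were not well above background on any gad1/2/4/5 array. Without ABA, GAD1 was at least 6.18-fold lower there than in Col-0 (limma, adjusted p = 3.03e-06) and GAD4 at least 7.93-fold lower (limma, adjusted p = 5.49e-10). With ABA the bounds were 5.46-fold for GAD1 (adjusted p = 2.78e-07) and 1.41-fold for GAD4 (adjusted p = 2.12e-05). GAD5 (AT3G17760) went the other way. It was not well above background in Col-0 and was at least 5.72-fold higher in control gad1/2/4/5 (limma, adjusted p = 7.74e-11), and at least 8.89-fold higher with ABA (adjusted p = 5.46e-11). The label gad1/2/4/5 is thus borne out by the transcripts of GAD1, GAD2 and GAD4 and not by that of GAD5. The labels do not say where the mutations lie, and a probe outside a disrupted part checks nothing. In gad2 the limma fold changes of GAD1 (-0.48 ± 0.35, adjusted p = 0.599) and GAD4 (-0.74 ± 0.30, adjusted p = 0.356) did not pass the test in control plants, and GAD5, above background on 1 of 4 control gad2 arrays and on 0 of 4 of Col-0, cannot be compared. GAD3 was not well above background in any group. A second GAD1 probe, above background on 1 of the 24 arrays, a control gad1/2/4/5 array, gave 1.47 (log2, gad1/2/4/5 against Col-0, control), the opposite sign, between signals mostly at background. With normexp the GAD1 and GAD5 calls were lost (adjusted p = 0.425 and 0.35 without ABA).

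ABA changed 4194 of the 19246 genes in Col-0 (limma), 2081 up and 2113 down. Among them, 1315 changed at least 2-fold, 886 up and 429 down. The largest rises among named genes were those of SWEET15, a sugar transporter (6.05 ± 1.07, adjusted p = 0.000299, above background on 3 of 4 control arrays), TSPO, a membrane protein induced by ABA (5.81 ± 0.37, adjusted p = 9.57e-10), and LEA7, a late embryogenesis abundant protein (5.41 ± 0.67, adjusted p = 4.46e-06). LEA4-5 and LEA18 were not well above background without ABA and rose at least 31.1-fold and at least 8.03-fold. The lipid transfer protein LTP4 rose by 4.72 ± 0.45 and CSLG2 by 4.16 ± 0.32. AACT1 fell by 4.49 ± 0.50 (adjusted p = 1.09e-06). The wall genes XTH31 (-3.42 ± 0.40) and EXPA8 (-2.90 ± 0.48) fell, as did ORA59, a jasmonate and ethylene response factor (-2.75 ± 0.42), CYP81F2 of indole glucosinolate metabolism (-2.67 ± 0.27), TDR1 (-2.99 ± 0.29) and DIN11 (-2.77 ± 0.39).

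Lists tied to ABA moved together in Col-0. All 7 tested PP2C phosphatases of ABA signalling rose (7 adjusted over the list alone, camera, adjusted p = 8.79e-16, and 0.00182 with an estimated correlation), among them HAI1 (4.42 ± 0.25), HAI2 (3.46 ± 0.15) and AHG3 (2.51 ± 0.16). All 32 ABA and drought marker genes rose (32 adjusted over the list alone, camera, adjusted p = 4.65e-36, and 0.00121 with an estimated correlation). All 8 cuticular wax genes rose (8 adjusted over the list alone, camera, adjusted p = 1.25e-12, and 0.00283 with an estimated correlation), with KCS2, an elongase of very long fatty acids, at 3.42 ± 0.23, the wax ester synthase WSD1 at 3.12 ± 0.24 and CER1 of alkane synthesis at 3.09 ± 0.20. Of 16 genes of ABA synthesis, breakdown and transport, 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera, adjusted p = 0.000443, and 0.00905 with an estimated correlation). The rises included the ABA hydroxylases CYP707A2 (3.18 ± 0.17), CYP707A1 (2.90 ± 0.34) and CYP707A3 (2.39 ± 0.25), which break ABA down. Of 10 ABA kinases and transcription factors, 4 rose (5 adjusted over the list alone, camera, adjusted p = 5.73e-05, and 0.0397 with an estimated correlation), namely SNRK2.7, ABI5, ABF3 (2.05 ± 0.17) and ABF2 (1.07 ± 0.13). Of 9 ABA receptors, 2 fell (2 adjusted over the list alone, camera, adjusted p = 0.0156). PYL6 fell at least 4.41-fold, to below background, and PYL4 by 2.15 ± 0.19. This receptor call was lost at adjusted p = 0.221 with an estimated correlation.

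Further lists were called in Col-0 with the preset correlation only. In the senescence and chlorophyll list 8 of 12 rose (8 adjusted over the list alone, camera, adjusted p = 4.19e-06, but adjusted p = 0.0624 with an estimated correlation), including the transcription factors NAP (2.19 ± 0.26) and ORE1 (2.11 ± 0.25) and SAG13 (1.65 ± 0.28). Sugar starvation genes rose in 6 of 10 cases (7 adjusted over the list alone, camera, adjusted p = 0.000128, but adjusted p = 0.145 with an estimated correlation), with asparagine synthetase ASN1 at 2.06 ± 0.42, MIOX2 at 1.59 ± 0.46 and DRM1 at 1.14 ± 0.18. In the salicylic acid and defence list 8 of 27 fell (8 adjusted over the list alone, camera, adjusted p = 0.000675, but adjusted p = 0.5 with an estimated correlation), among them PAD3 of camalexin synthesis (-1.93 ± 0.34), WRKY46 (-1.27 ± 0.37) and WRKY53 (-1.16 ± 0.23). The glucosinolate list had 4 of 16 genes lower (9 adjusted over the list alone, camera, adjusted p = 0.00254, but adjusted p = 0.468 with an estimated correlation), including the regulator MYB51 (-0.92 ± 0.25). Of 15 flavonoid and anthocyanin genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera, adjusted p = 0.00582, but adjusted p = 0.468 with an estimated correlation). The anthocyanin regulator PAP1 rose by 1.44 ± 0.28, and PAP2 rose at least 2.21-fold.

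Other lists showed no shift as a group in Col-0. In the GABA shunt, glutamate and GABA transport list 3 of 14 rose and 2 fell (5 and 3 adjusted over the list alone, camera, adjusted p = 0.396). POP2, the transaminase that breaks GABA down, rose by 1.24 ± 0.14 (adjusted p = 1.24e-06), the GABA transporter GAT1 rose (adjusted p = 0.000344), and the amino acid permease AAP3 fell by 1.13 ± 0.23. GAD4 was the 1 GAD gene of 4 to change, with a fall of -1.99 ± 0.30 (adjusted p = 5.76e-05; 1 adjusted over the list alone, camera for the GAD family, adjusted p = 0.458). Among 22 genes of stomatal CO2 and ion transport signalling, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera, adjusted p = 0.705), with the outward potassium channel GORK at 1.08 ± 0.30, the anion channel SLAH3 at 0.73 ± 0.20 and the inward potassium channel AKT1 at -1.25 ± 0.24. Of 9 guard cell markers 1 rose and 2 fell, including MYB60, a guard cell transcription factor (-0.95 ± 0.14; 1 and 2 adjusted over the list alone, camera, adjusted p = 0.879). Jasmonate genes rose in 1 and fell in 7 of 27 cases (1 and 7 adjusted over the list alone, camera, adjusted p = 0.0977). Clock genes rose in 4 and fell in 1 of 20 cases (5 and 1 adjusted over the list alone, camera, adjusted p = 0.136), with CCA1 at 1.38 ± 0.23 and ELF4 at 1.00 ± 0.18. Auxin and wall expansion genes fell in 2 of 21 cases, EXPA8 and EXPA5 (-1.12 ± 0.23; 2 adjusted over the list alone, camera, adjusted p = 0.449), and heat shock genes in 2 of 10, with HSP90.1 at -1.32 ± 0.39 (2 adjusted over the list alone, camera, adjusted p = 0.208). Among floral markers 1 of 5 rose and among phloem and epidermis markers 1 of 4 rose (1 and 1 adjusted over the list alone, camera, adjusted p = 0.208 and 0.241). Of 23 light harvesting genes 0 changed in limma or adjusted over the list alone (camera, adjusted p = 0.449).

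Within scan days 1, 2 and 3, 97.9%, 99.9% and 99.2% of the 4194 genes kept the sign. Such shares, here and for later comparisons, are high by construction, since the genes were called on these same arrays. The PP2C list's mean shift was 2.41, with 2.39, 2.55 and 2.39 within those days, and that of the marker genes 2.21, with 2.05, 2.45 and 2.32. With scan day as a block 3846 genes were called. With slide as a fixed block, on 3 residual degrees of freedom, 0 were called by limma, against 2717 with normexp and 6443 at an unadjusted p under 0.05 in the fit without a block.

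In gad2, ABA changed 5586 genes (limma), 2782 up and 2804 down, of which 1660 changed at least 2-fold, 1071 up and 589 down. SWEET15 rose by 6.76 ± 1.07 (adjusted p = 8.07e-05, above background on 3 of 4 control arrays), TSPO by 5.63 ± 0.37 (adjusted p = 1.52e-09), LEA7 by 5.60 ± 0.67 and LTP4 by 4.73 ± 0.45. FPF1, a flowering promoting factor, rose at least 15.4-fold (adjusted p = 5.99e-08) and LEA18 at least 16.0-fold. The glyoxalase GLYI7 rose by 4.94 ± 0.66. EXPA8 fell by 4.89 ± 0.48 (adjusted p = 2.26e-07, above background on 3 of 4 ABA arrays), AACT1 by 4.04 ± 0.50, XTH31 by 3.30 ± 0.40 and CYP81F2 by 2.53 ± 0.27.

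All 7 PP2C phosphatases rose in gad2 (7 adjusted over the list alone, camera, adjusted p = 2.2e-12, and 0.00627 with an estimated correlation), with HAI1 at 4.23 ± 0.25 and HAI2 at 2.77 ± 0.15. All 32 marker genes rose (32 adjusted over the list alone, camera, adjusted p = 1.46e-28, and 0.00431 with an estimated correlation), with LEA4-5 at 4.01 ± 0.38. Wax genes rose in 7 of 8 cases (7 adjusted over the list alone, camera, adjusted p = 6.49e-07, and 0.0322 with an estimated correlation), with KCS2 at 2.42 ± 0.23, MAH1 at 1.90 ± 0.58 and CER1 at 1.73 ± 0.20. Of 16 genes of ABA synthesis, breakdown and transport, 6 rose and 2 fell (6 and 3 adjusted over the list alone, camera, adjusted p = 0.00286, and 0.0322 with an estimated correlation), with CYP707A1 at 3.27 ± 0.34. Senescence genes rose in 8 of 12 cases (8 adjusted over the list alone, camera, adjusted p = 6.49e-07, and 0.0486 with an estimated correlation), with SAG13 at 2.25 ± 0.28. The kinases and transcription factors (4 up and 1 down of 10; 5 and 1 adjusted over the list alone, camera, adjusted p = 0.00127, but adjusted p = 0.106 with an estimated correlation) included ABI5 at 1.94 ± 0.29. Sugar starvation genes (6 up of 10; 6 adjusted over the list alone, camera, adjusted p = 0.000154, but adjusted p = 0.152 with an estimated correlation) included ASN1 at 2.31 ± 0.42. Flavonoid genes rose in 7 of 15 cases, 13 adjusted over the list alone (camera, adjusted p = 0.000119, but adjusted p = 0.303 with an estimated correlation), and PAP1 rose by 1.61 ± 0.28. Defence genes fell in 7 of 27 cases (7 adjusted over the list alone, camera, adjusted p = 0.00934, but adjusted p = 0.673 with an estimated correlation), including EDS1 at -1.38 ± 0.32. The defence list's mean was 0.12 on ABA-treated gad2 replicate 2, against 1.19 to 1.41 on the other arrays of that group. Its shift of -0.44 was -0.50 and -0.42 within scan days 1 and 3. Within slide K, which held that array, it was -1.45, and within slide M 0.12.

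Several gad2 lists did not shift as a group. The receptors PYL4 (-1.98 ± 0.19) and PYL2 (-2.07 ± 0.31, above background on 1 of 4 ABA arrays) were among 4 receptors that fell, and 1 rose, of 9 (1 and 4 adjusted over the list alone, camera, adjusted p = 0.0702). In the GABA shunt list 4 rose and 1 fell of 14 (4 and 2 adjusted over the list alone, camera, adjusted p = 0.277), with POP2 at 1.58 ± 0.14, GAT1 at 1.19 ± 0.20 and glutamate dehydrogenase GDH1 at -0.93 ± 0.24. GAD4 fell by 1.85 ± 0.30 (adjusted p = 0.000115, above background on 1 of 4 ABA arrays), and the GAD family as a list was not called (1 adjusted over the list alone, camera, adjusted p = 0.809). In the stomatal CO2 and ion transport list 2 rose and 4 fell of 22 (2 and 4 adjusted over the list alone, camera, adjusted p = 0.137), with AKT1 at -1.60 ± 0.24, the carbonic anhydrase CA4 at -0.57 ± 0.11 and SLAH3 at 0.57 ± 0.20. Guard cell markers had 1 rise and 2 falls among 9 (1 and 2 adjusted over the list alone, camera, adjusted p = 0.088), and MYB60 fell by 1.26 ± 0.14. MPK12 is in both of these lists and was called with a rise, but it was not well above background on any gad2 array. Within scan days 1 and 3, 99.2% and 100% of the 5586 genes kept the sign, and 98.4% and 97.9% within slides K and M. The PP2C shift of 2.17 was 1.88 and 2.23 within those days, and 4990 genes were called with scan day as a block against 922 with slide as a fixed block and 3591 with normexp.

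In gad1/2/4/5, ABA changed 4371 genes (limma), 2115 up and 2256 down, of which 1429 changed at least 2-fold, 878 up and 551 down. TSPO rose by 6.40 ± 0.37 (adjusted p = 2.28e-10), LEA7 by 5.78 ± 0.67, SWEET15 by 5.78 ± 1.07, LTP4 by 5.49 ± 0.45 and HAI1 by 5.03 ± 0.25 (adjusted p = 1.54e-11). AFP1, a binding partner of ABI5, rose by 4.41 ± 0.19 (adjusted p = 1.25e-12) and MYB45 at least 10.4-fold. PYL6 fell at least 4.46-fold and EXPA8 by 3.65 ± 0.48, while AACT1 (-3.57 ± 0.50) and ORA59 (-2.66 ± 0.42) fell as well.

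In gad1/2/4/5, 4 ABA lists were called by camera with a preset and an estimated correlation. They were the 7 PP2C phosphatases (7 up; 7 adjusted over the list alone, but adjusted p = 1.79e-16 and 0.00145 with an estimated correlation), the marker genes (29 of 32 up; 30 adjusted over the list alone, but adjusted p = 8.42e-36 and 0.00126 with an estimated correlation), the wax genes (7 of 8 up; 8 adjusted over the list alone, but adjusted p = 5.71e-11 and 0.00565 with an estimated correlation) and ABA synthesis, breakdown and transport (7 up and 1 down of 16; 8 and 1 adjusted over the list alone, but adjusted p = 0.00052 and 0.00986 with an estimated correlation). KCS2 rose by 3.49 ± 0.23, MAH1 by 2.83 ± 0.58 and CYP707A1 by 2.67 ± 0.34. Senescence genes rose in 7 of 12 cases (8 adjusted over the list alone, camera, adjusted p = 1.33e-06, but adjusted p = 0.0585 with an estimated correlation), with ORE1 at 2.01 ± 0.25. ABA kinases and transcription factors rose in 5 of 10 cases (5 adjusted over the list alone, camera, adjusted p = 0.000439, but adjusted p = 0.0647 with an estimated correlation), with ABI5 at 2.23 ± 0.29. Sugar starvation genes rose in 4 of 10 cases (5 adjusted over the list alone, camera, adjusted p = 0.00198, but adjusted p = 0.267 with an estimated correlation), with MIOX2 at 1.68 ± 0.46. Receptors fell in 3 of 9 cases (4 adjusted over the list alone, camera, adjusted p = 0.00781, but adjusted p = 0.18 with an estimated correlation), with PYL4 at -2.44 ± 0.19. Jasmonate genes rose in 10 and fell in 1 of 27 cases (10 and 1 adjusted over the list alone, camera, adjusted p = 0.00052, but adjusted p = 0.462 with an estimated correlation), including the storage proteins VSP2 (1.60 ± 0.42) and VSP1 (1.57 ± 0.45) and CYP94B3, which inactivates the jasmonate hormone (2.49 ± 0.49).

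Auxin and wall expansion genes fell in 6 and rose in 1 of 21 cases in gad1/2/4/5 (6 and 1 adjusted over the list alone, camera, adjusted p = 0.0127, but adjusted p = 0.515 with an estimated correlation), with SAUR15 at -1.45 ± 0.36. Light harvesting genes fell in 3 of 23 cases, 2 adjusted over the list alone (camera, adjusted p = 0.00474, but adjusted p = 0.655 with an estimated correlation), with LHCB4.3 at -0.88 ± 0.22, LHCA6 at -0.71 ± 0.20 and the Rubisco activase RCA at -0.43 ± 0.15. In the GABA shunt list 3 rose and 3 fell of 14 (3 and 4 adjusted over the list alone, camera, adjusted p = 0.328), with POP2 at 1.41 ± 0.14, GAT1 at 1.27 ± 0.20, AAP3 at -1.05 ± 0.23 and GDH1 at -0.81 ± 0.24. Stomatal CO2 and ion transport genes rose in 1 and fell in 5 of 22 cases (1 and 5 adjusted over the list alone, camera, adjusted p = 0.382), and guard cell markers fell in 4 of 9 (4 adjusted over the list alone, camera, adjusted p = 0.12), with MYB60 at -1.59 ± 0.14. PAP2 rose at least 4.29-fold and PAP1 by 2.48 ± 0.28, within a flavonoid list that was not called (2 up and 1 down of 15; 2 and 1 adjusted over the list alone, camera, adjusted p = 0.0812). The 4 ABA arrays of this genotype shared 1 slide and 1 scan day with no other group, so treatment, slide and day cannot be told apart, and 2482 genes were called in a fit of only the groups compared.

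The ABA responses of the 3 genotypes overlapped. Of 7830 genes called in at least 1 genotype, 2201 were called in all 3, 1362 up and 839 down, with 0 of them in opposite directions. Col-0 and gad2 shared 3064 called genes and Col-0 and gad1/2/4/5 shared 2609. Over 19246 genes the log2 changes in Col-0 correlated with those in gad2 at r = 0.82 (Spearman 0.734) and with those in gad1/2/4/5 at r = 0.791 (Spearman 0.674). The mutants correlated with each other at r = 0.798 (Spearman 0.707). These correlations are across genes, which are not independent replicates, and each genotype had its own control arrays. Of the 4194 genes called in Col-0, 98.7% had the same sign in gad2 and 97.1% in gad1/2/4/5. Calls in 1 genotype alone numbered 722 in Col-0, 1874 in gad2 and 1114 in gad1/2/4/5, and such a count does not show a difference in response.

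**Figure D1:**
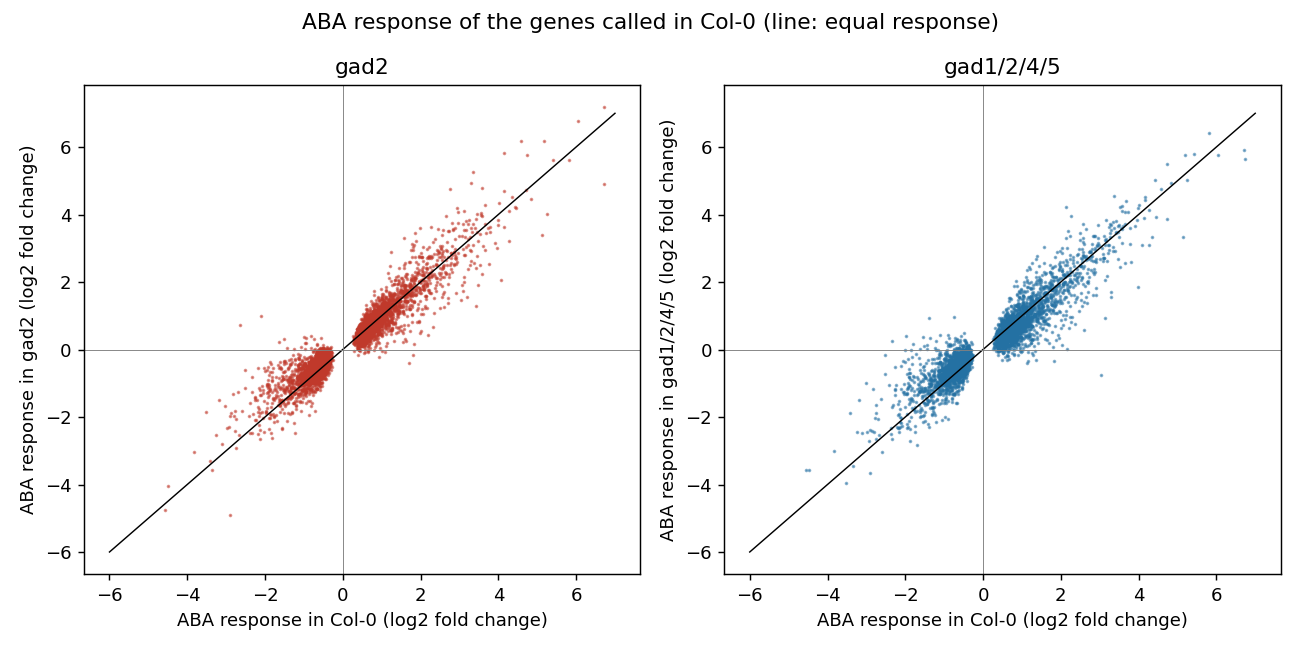
Log2 fold change after ABA in gad2 (left, vertical axis) and gad1/2/4/5 (right, vertical axis) against that in Col-0 (horizontal axis), with 1 point for each of the 4194 genes called in Col-0 and a line of equal response. In gad2 98.7% of the genes and in gad1/2/4/5 97.1% lie on the same side of 0 as in Col-0.

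The difference in ABA response between genotypes was tested directly. For gad2 against Col-0, limma called 0 genes, 764 had an unadjusted p under 0.05 against 962 from chance, and the smallest adjusted p was 0.889. For gad1/2/4/5 against Col-0 limma also called 0 genes, 1252 had an unadjusted p under 0.05 and the smallest adjusted p was 0.189, that of GAD4 (2.38 ± 0.43), which is below background in the mutant. Both counts were also 0 in every other fit over all 24 arrays, including slide as a random block, while scan day and slide as fixed blocks could not be fitted for gad1/2/4/5. Over the 1315 genes with at least a 2-fold ABA response in Col-0, the median 95% interval of the difference reached 0.79 to either side. That interval is for a single gene, whereas calls were adjusted over all genes tested and so needed larger differences. The counts of 0 thus do not exclude differences above 0.79, and that of GAD4, at 2.38, was not called. Wax genes responded less in gad2 than in Col-0 (mean difference -0.82; 0 of 8 called by limma, 4 down adjusted over the list alone, camera, adjusted p = 4.11e-07). This call was lost at adjusted p = 0.0841 with an estimated correlation. The mean of the wax list was -1.095 in control and 1.163 in ABA-treated Col-0, and 0.015 and 1.451 in gad2. The smaller response thus went with a higher control level, and the level with ABA was not lower in gad2. In gad1/2/4/5 jasmonate genes had a mean difference of 0.76 (0 of 27 called by limma, 9 up adjusted over the list alone, camera, adjusted p = 9.38e-16, but adjusted p = 0.138 with an estimated correlation). Glucosinolate genes had 0.57 (0 of 16 called by limma, 6 up adjusted over the list alone, camera, adjusted p = 1.04e-10, but adjusted p = 0.138 with an estimated correlation), and light harvesting genes -0.45 (0 of 23, camera, adjusted p = 1.32e-07, but adjusted p = 0.507 with an estimated correlation). Slide and day are confounded with the ABA group of gad1/2/4/5 in these differences.

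Without ABA, gad2 differed from Col-0 in 94 genes (limma), 55 higher and 39 lower, 64 of them at least 2-fold. The largest differences were in MPK12 and BPS2, neighbours on chromosome 2. MPK12 (AT2G46070), a MAP kinase of guard cells that acts in stomatal CO2 signalling, was at least 32.3-fold lower in gad2, where it was not well above background (limma, adjusted p = 2.12e-17). BPS2 (AT2G46080) was lower by a log2 fold change of -8.72 ± 0.47 (adjusted p = 2.9e-10) and above background on 3 of 4 gad2 arrays. In gad1/2/4/5 these genes differed from Col-0 by -0.08 and -0.02 (adjusted p = 0.949 and 0.998), and among the 20 nearest tested genes 0 were called by limma in gad2, the largest difference being 0.64. TPX2 (AT1G65970), a peroxiredoxin gene next to GAD2, was higher in gad2 by 3.86 ± 0.29 (adjusted p = 4.49e-08). The authors' deposited table lists wild type over gad2 folds of 15.1 for GAD2, 21.1 for MPK12 and 190 for BPS2, and -15.2 for TPX2. The fold for MPK12 is smaller than the bound of 32.3 given here, which thus holds only on the scale of the processed signal. The authors' deposited table has 54 entries for this comparison, and 49 of its genes were called here, all 49 with the same sign.

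**Figure D2:**
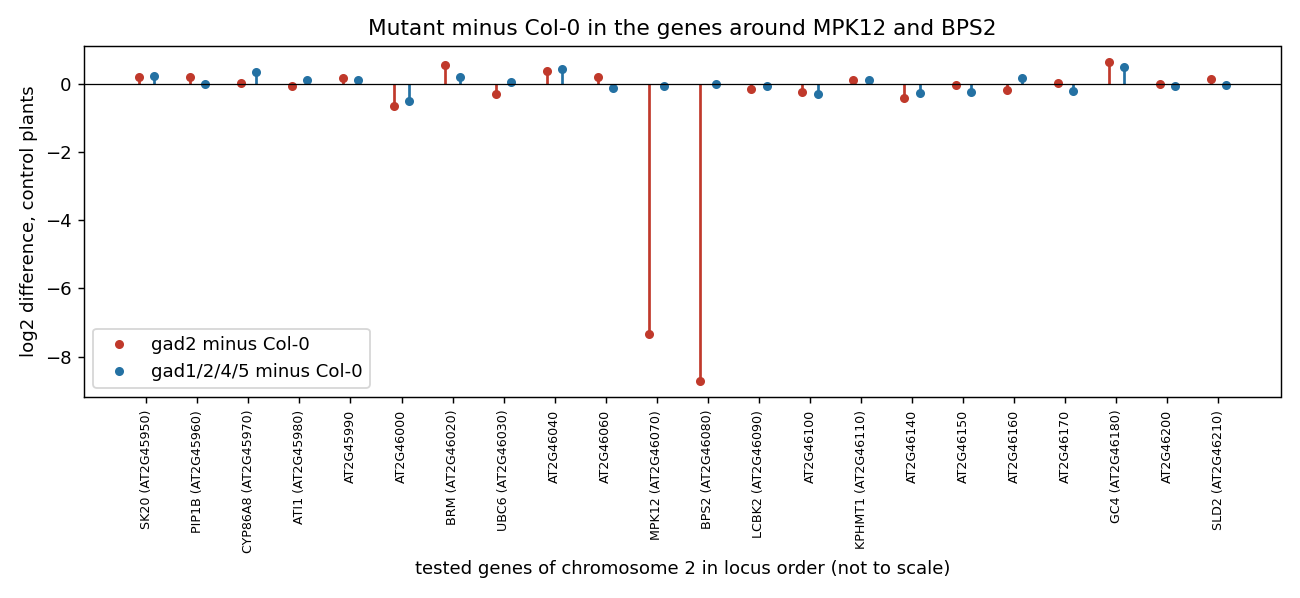
Log2 difference from Col-0 in control plants (vertical axis) for tested genes of chromosome 2 in locus order around MPK12 and BPS2 (horizontal axis, not to scale), in gad2 (red) and gad1/2/4/5 (blue). In gad2, MPK12 (below background, at least 32.3-fold lower) and BPS2 (-8.72) lie lowest, and the other 20 genes stay within 0.64 of 0.

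Cuticular wax genes were higher in control gad2 than in control Col-0, 4 of 8 called and 6 adjusted over the list alone (mean 1.11, camera, adjusted p = 5.39e-12, and 0.00904 with an estimated correlation). CER4, a fatty acyl reductase, was higher by 1.74 ± 0.27 (adjusted p = 0.00211), CER1 by 1.73 ± 0.20 (adjusted p = 6.98e-05), WSD1 by 1.72 ± 0.24 (adjusted p = 0.00121) and KCS2 by 1.53 ± 0.23 (adjusted p = 0.00178). The wax shift was 0.98, 1.41 and 1.03 within scan days 1, 2 and 3 and 1.15 within the shared slide. Further higher genes were HSFA6A, a heat shock factor (2.58 ± 0.34) and DAA1 (2.52 ± 0.30), each above background on 1 of 4 Col-0 arrays, and the seed regulator FUS3 (1.74 ± 0.26). LEA4-5 and ORP4B, below background in Col-0, were at least 2.84-fold and at least 1.48-fold higher. MES7 (-1.63 ± 0.36, adjusted p = 0.0405) and AAP3 (-1.09 ± 0.23, adjusted p = 0.0354) were lower, and AAP3 was the 1 called gene of the 14 in the GABA shunt list (2 up and 1 down adjusted over the list alone, camera, adjusted p = 0.844).

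Other lists shifted in control gad2 by camera with the preset correlation only. Jasmonate genes were lower (mean -0.53; 2 of 27 called, JAZ7 at -1.25 ± 0.24 and the repressor JAZ2 at -0.91 ± 0.20; 8 adjusted over the list alone, camera, adjusted p = 2.47e-09, but adjusted p = 0.127 with an estimated correlation). Within scan days 1, 2 and 3 the mean was -0.53, -0.35 and -0.49. Sugar starvation genes were lower (mean -0.63; 1 of 10 called, DRM1 at -0.87 ± 0.18; 6 adjusted over the list alone, camera, adjusted p = 7.91e-06, but adjusted p = 0.127 with an estimated correlation). PP2C phosphatases were higher (mean 0.40; 1 of 7 called, HAI2 at 1.05 ± 0.15; 1 adjusted over the list alone, camera, adjusted p = 7.37e-05, but adjusted p = 0.127 with an estimated correlation). Marker genes were higher (mean 0.28; 3 of 32 called, with LTP3 at 1.37 ± 0.25 and proline synthesis gene P5CS1 at 0.85 ± 0.19; 8 up and 3 down adjusted over the list alone, camera, adjusted p = 6.92e-05, but adjusted p = 0.249 with an estimated correlation). Receptors (0 of 9 called by limma, 1 up and 5 down adjusted over the list alone, camera, adjusted p = 0.00332, but adjusted p = 0.127 with an estimated correlation) had a mean of -0.42. Clock genes (1 of 20 called, CCA1 at 1.15 ± 0.23; 2 up and 1 down adjusted over the list alone, camera, adjusted p = 0.0185, but adjusted p = 0.249 with an estimated correlation) had a mean of 0.22. Of 22 stomatal CO2 and ion transport genes, 1 was called, MPK12 (3 up and 1 down adjusted over the list alone, camera, adjusted p = 0.227). Guard cell markers had MPK12 as the 1 called gene of 9, a mean of -0.49 and a median of 0.17 with opposite signs (2 up and 1 down adjusted over the list alone, camera, adjusted p = 0.842).

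All 94 genes called in control gad2 kept their sign within each of scan days 1, 2 and 3 and within the slide that held both groups. Counts were 77 with scan day as a block, 0 with slide as a fixed block on 3 residual degrees of freedom (limma; 2190 at an unadjusted p under 0.05 without a block), 29 with normexp, 59 with the authors' matrix and 542 with array weights, which held all 94. The split of 55 up and 39 down became 62 and 27 with quantile normalization, 42 and 17 with the authors' matrix and 22 and 7 with normexp. Leaving out Col-0 control replicate 2, 3 or 4 or gad2 control replicate 2 gave 45, 58, 59 or 52 genes.

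In control gad1/2/4/5, 67 genes differed from Col-0 (limma), 23 higher and 44 lower, 46 of them at least 2-fold. Beside the GAD genes, TPX2 was higher by 4.52 ± 0.29 (adjusted p = 2.12e-09), TBL15 by 2.15 ± 0.33 (adjusted p = 0.00393, above background on 3 of 4 Col-0 arrays), the brassinosteroid-inactivating enzyme BAS1 by 1.45 ± 0.31 (adjusted p = 0.0443), CER4 by 1.29 ± 0.27, the expansin EXPB1 by 1.22 ± 0.26 and the kinase WAG1 by 0.93 ± 0.18. BSMT1, which makes methyl salicylate, was lower by -1.83 ± 0.31 (adjusted p = 0.0126), the galactinol synthase GolS1 by -1.60 ± 0.33, AAE12 by -1.37 ± 0.26 and the drought-induced factor RD26 by -0.87 ± 0.19. The authors' deposited table has wild type over mutant folds of 11.9 for GAD2, 3.05 for GAD1, 6.04 for GAD4, -4.67 for GAD5 and -22.7 for TPX2. For GAD1, GAD4 and GAD5 these folds are smaller in size than the bounds given above, which hold only on the scale of the processed signal. Of the 50 entries in the authors' deposited table for this comparison, 34 genes were called here, all 34 with the same sign.

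Jasmonate genes were lower in control gad1/2/4/5 (mean -0.75; 3 of 27 called, 22 adjusted over the list alone, camera, adjusted p = 2.98e-22, and 0.0219 with an estimated correlation). The called genes were the repressors JAZ5 (-1.24 ± 0.26, adjusted p = 0.0429) and JAZ2 (-1.04 ± 0.20, adjusted p = 0.0342) and OPR3 of jasmonate synthesis (adjusted p = 0.0415). Within scan days 2 and 3 the list's mean was -0.52 and -0.63, and -0.59 with scan day as a block. The GAD family had 1 gene higher and 3 lower of 4 (1 and 3 adjusted over the list alone, camera, adjusted p = 1.94e-07, and 0.00128 with an estimated correlation). Glucosinolate genes were lower (mean -0.38; 1 of 16 called, CYP79B3 at -0.96 ± 0.21; 5 adjusted over the list alone, camera, adjusted p = 1.03e-07, but adjusted p = 0.172 with an estimated correlation). PP2C phosphatases were lower (mean -0.39; 0 of 7 called by limma, 3 adjusted over the list alone, camera, adjusted p = 5.34e-05, but adjusted p = 0.169 with an estimated correlation), as were marker genes (mean -0.30; 1 of 32 called, RD26; 2 adjusted over the list alone, camera, adjusted p = 1.11e-05, but adjusted p = 0.297 with an estimated correlation). Auxin and wall expansion genes were higher (mean 0.48; 0 of 21 called by limma, 3 adjusted over the list alone, camera, adjusted p = 0.000244, but adjusted p = 0.371 with an estimated correlation). The senescence and chlorophyll list was also called as lower by camera with the preset correlation (mean -0.27). Its sign turned between scan days, with a mean of -0.16 within day 2 and 0.39 within day 3.

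Counts for control gad1/2/4/5 moved with the setting. They were 14 with scan day as a block, 0 with slide as a fixed block (limma; 1776 at an unadjusted p under 0.05 without a block), 35 with quantile normalization, 18 with no filter on dim probes, 11 with normexp and 162 with array weights, and all 67 genes kept their sign within scan days 2 and 3. Leaving out any of 7 of the 8 arrays lowered the count by over 1.5-fold, to 12 without Col-0 control replicate 2, and to 29 or 20 without Col-0 control replicate 3 or 4. It was 26, 24, 31 and 35 without gad1/2/4/5 control replicates 1 to 4.

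The differences of the mutants from control Col-0 share the Col-0 arrays. Over 19246 genes they correlated at r = 0.554 (Spearman 0.51). Unchanged groups that shared simulated Col-0 arrays gave 0.5 (Spearman 0.463), with a highest value of 0.524 in 100 simulations. Each gene was drawn independently there, without the correlation between genes of real arrays, so the simulated ranges may be too narrow. They cannot decide whether the observed values exceed chance. The covariance was 0.0669, against 0.0375 simulated. With the Col-0 arrays split between the comparisons, r lay between 0.022 and 0.354. Both mutants had 7 called genes higher and 9 lower. Independent lists, which leave out the shared arrays, give 0.0657 and 0.0892. Lists of the same sizes, ranked in the same simulations, shared a mean of 2.38 and 3.0 genes, with a highest of 6 in either direction, and the same limit holds. Higher in both were TPX2, CER4, EXPB1 and WAG1, together with AT2G22270, AT2G43870 and AT5G11330. Lower in both were GAD2, JAZ2, EXL2, EPS1, SEH and TBL37, with AT1G23850, AT2G45930 and AT5G58680. EXL2, EPS1, SEH, TBL37 and the genes without symbols were named after their values were seen.

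With ABA, gad2 differed from Col-0 in 10 genes (limma), 5 higher and 5 lower. GAD2 was lower by -3.54 ± 0.21 (adjusted p = 7.99e-10), MPK12 at least 24.9-fold lower (adjusted p = 7.46e-17) and BPS2 lower by -8.10 ± 0.47 (adjusted p = 8.89e-10). TPX2 was higher by 4.73 ± 0.29 (adjusted p = 8.89e-10) and SMP1 by 1.82 ± 0.32 (adjusted p = 0.0227, above background on 2 of 4 Col-0 arrays). No list was called with an estimated correlation. Sugar starvation genes were lower with the preset one (mean -0.53; 0 of 10 called by limma, 4 adjusted over the list alone, camera, adjusted p = 4e-06, but adjusted p = 0.108 with an estimated correlation). Guard cell markers had a mean of -0.91 and a median of -0.08, with MPK12 as the 1 called gene of 9 (1 adjusted over the list alone, camera, adjusted p = 8.29e-05, but adjusted p = 0.0974 with an estimated correlation). All 10 genes kept their sign within scan days 1 and 3. Counts were 9 with scan day as a block, 0 with slide as a fixed block (limma; 1361 at an unadjusted p under 0.05 without a block), 5 with normexp, 24 with array weights and 6 without gad2 ABA replicate 1 or 4.

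With ABA, gad1/2/4/5 differed from Col-0 in 11 genes (limma), 6 higher and 5 lower. GAD1, GAD2 and GAD4 were lower and GAD5 higher, with GAD2 at -3.34 ± 0.21 (adjusted p = 1.64e-09), and TPX2 was higher by 4.98 ± 0.29 (adjusted p = 6.39e-10). The GAD family was the 1 list called with an estimated correlation (1 higher and 3 lower of 4; 1 and 3 adjusted over the list alone, camera, adjusted p = 1.26e-05, and 0.00531 with an estimated correlation). Light harvesting genes had a mean of -0.38 (0 of 23 called by limma, 3 lower adjusted over the list alone, camera, adjusted p = 1.26e-07, but adjusted p = 0.549 with an estimated correlation), and the authors' matrix gave 0.02 with the sign turned. Slide and day cannot be told apart from the mutant here, and 6 genes were called with normexp and 37 with no filter on dim probes.

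Between the mutants without ABA, 84 genes differed (limma), 29 higher in gad1/2/4/5 than in gad2 and 55 lower, 60 of them at least 2-fold. BPS2 was higher in gad1/2/4/5 by 8.70 ± 0.47 and MPK12 at least 30.6-fold (adjusted p = 2.62e-17). GAD5 was higher by 3.60 ± 0.22 (above background on 1 of 4 gad2 arrays), and GAD4 and GAD1 were at least 4.75-fold and at least 4.44-fold lower, while GAD2 differed by 0.35 ± 0.21 (adjusted p = 0.642). PP2C phosphatases were lower in gad1/2/4/5 than in gad2, 2 of 7 called and 6 adjusted over the list alone (mean -0.78, camera, adjusted p = 1.66e-13, and 0.00818 with an estimated correlation), with HAI2 at -1.72 ± 0.15 (adjusted p = 4.57e-07) and HAI1 at -1.49 ± 0.25 (adjusted p = 0.00497). Marker genes were lower, 4 of 32 called and 18 adjusted over the list alone (mean -0.58, camera, adjusted p = 1.15e-17, and 0.016 with an estimated correlation), among them LTP3 (-1.86 ± 0.25) and the dehydrins RAB18 (-1.08 ± 0.22) and ERD10 (-0.70 ± 0.15). Wax genes were lower, 3 of 8 called and 3 adjusted over the list alone (mean -0.81, camera, adjusted p = 1.05e-08, and 0.016 with an estimated correlation), with WSD1 at -2.02 ± 0.23, CER1 at -1.29 ± 0.20 and KCS2 at -1.23 ± 0.23. Receptors were higher, 2 of 9 called and 5 adjusted over the list alone (mean 0.54, camera, adjusted p = 0.000684, but adjusted p = 0.0855 with an estimated correlation), namely PYL6 (2.16 ± 0.48, above background on 3 of 4 gad2 arrays) and PYL5 (1.46 ± 0.30). MYB70 (1.17 ± 0.20) and AAP3 (1.05 ± 0.23) were higher, and the starch synthase GBSS1 was lower by -1.51 ± 0.25.

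Within scan days 2 and 3 the PP2C mean of this last comparison was -0.67 and -0.77, that of marker genes -0.72 and -0.41, and that of wax genes -0.67 and -0.92. Within slides H, K and M the PP2C mean was -0.58, -0.58 and -0.97, and that of marker genes -0.76, -0.13 and -0.69. All 84 genes kept their sign within both days, and 97.6% did within slide K. The count was 76 with scan day as a block, 5 with slide as a fixed block, 40 with normexp, 490 with array weights, and 55, 53 or 42 without gad2 control replicate 1, 2 or 4 and 53 without gad1/2/4/5 control replicate 2. The authors' deposited table has 58 entries here, and 52 of its genes were called, all 52 with the same sign.

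**Figure D3:**
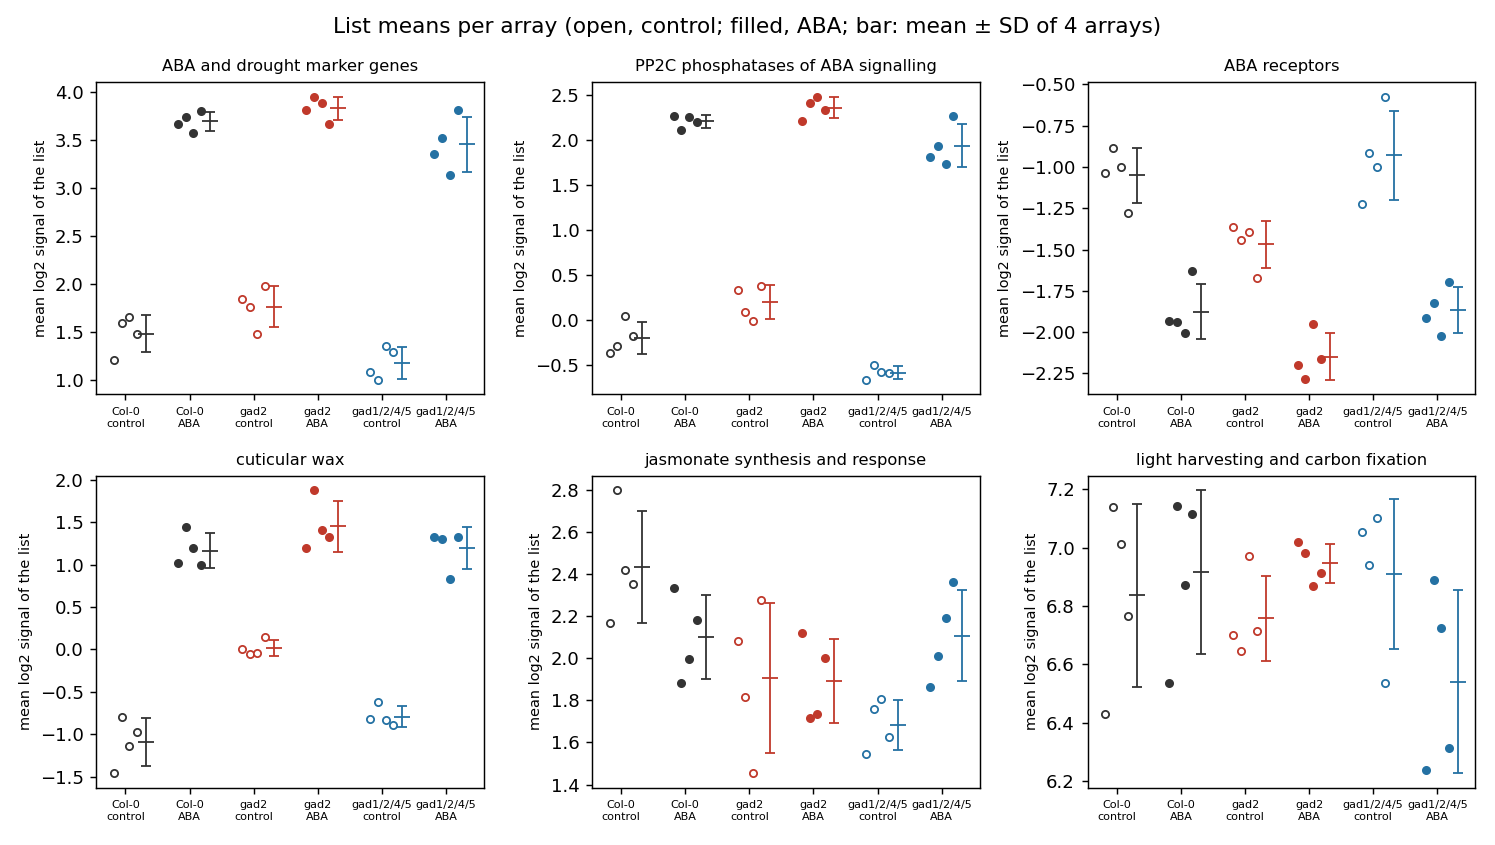
Mean log2 signal of 6 gene lists (vertical axes) on each array of the 6 groups (horizontal axis), open circles for control, filled circles for ABA, and bars for the mean ± SD of 4 arrays. Marker, PP2C and wax genes lie higher on ABA arrays of all 3 genotypes, and wax genes of control gad2 lie 1.11 above those of control Col-0.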

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

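The tests of the 3 patterns weighed here were chosen only after the results were seen, while the counts over other splits of the arrays were planned. MPK12 and BPS2 were far lower in both gad2 groups, with MPK12 below background and BPS2 above it at 1 of its probes on 3 of 4 arrays per group. A fault of arrays or spots is excluded, since all 8 gad2 arrays lay below every other array measured, 16 at 2 of the 3 probes and 15 at a BPS2 probe. A base change under 1 probe alone cannot account for the whole pattern, since all 3 probes fell in gad2. The smallest difference of means over the 3 probes was -7.33 in control plants. That was for MPK12, which is below background in gad2. MPK12 had only 1 probe, so a base change under that probe is not excluded for MPK12 by itself. On the scale of the processed signal its fall was at least 32.3-fold without ABA and at least 24.9-fold with it. The authors' deposited fold for MPK12 without ABA is 21.1. A candidate explanation is a loss of both neighbouring genes in the gad2 line, since the nearest tested genes outside the pair, AT2G46060 and LCBK2, differed from Col-0 by at most 0.19 without ABA and 0.36 with ABA and did not pass the test. No DNA was measured, so this stays a hypothesis. In control gad1/2/4/5 the fall in GAD2 was -3.56, against -3.91 in control gad2. There MPK12 and BPS2 differed from Col-0 by -0.08 and -0.02 without ABA, and by -0.21 and -0.09 with it. These values argue against the fall in GAD2 transcript by itself as the cause, although gad1/2/4/5 also carries other mutations.

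PP2C, marker and wax genes were higher in control gad2 than in control gad1/2/4/5, which may reflect a difference in ABA response before treatment. A score of the genes that ABA changed at least 2-fold in Col-0 differed by -0.32 between the mutants (exact permutation p = 0.171), so neither a shift along the whole ABA response nor array scaling, with -0.33 after quantile normalization, was shown or excluded. Similar scores against control Col-0 used genes that ABA changed at least 2-fold in the other mutant. They differed by -0.08 in gad2 (exact permutation p = 0.629) and -0.32 in gad1/2/4/5 (exact permutation p = 0.229), and neither passed. The mutants shared slides and days, but the score between the mutants does not decide on these either. It was -0.76 and -0.06 within days 2 and 3, and -0.91, -0.27 and 0.14 within slides H, M and K. The 3 lists were picked because they were called on these same arrays, which favours the signs and intervals that follow by construction. For the lists themselves the mean differences, gad1/2/4/5 minus gad2, were below 0 within every shared day and slide. With scan day as a term their 95% intervals ended at -0.54 (PP2C), -0.30 (markers) and -0.45 (wax). With slide as a term, on 3 residual degrees of freedom, they ended at -0.30, 0.15 and -0.15, so slide as the whole cause stays undecided for the marker genes, as does whether these lists alone differ or the whole ABA response does.

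Against the same Col-0 control arrays, the mean of jasmonate genes was -0.75 in control gad1/2/4/5 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give) and -0.53 in control gad2. The gad2 difference did not pass this test (exact permutation p = 0.0571), and its camera call was lost at adjusted p = 0.127 with an estimated correlation. A single Col-0 array is excluded as the cause in gad1/2/4/5, since the mean stayed at or below -0.63 without any 1 of them. The mean stayed at or below -0.35 within each shared scan day, which argues against scan day as the whole cause. With only 1 or 2 arrays of a group per day, and a list picked from these same arrays, it does not exclude scan day. A genotype effect of the same size with and without ABA remains possible but undecided, as the gad2 difference changed by 0.32 from control to ABA (95% interval -0.18 to 0.82), while that of gad1/2/4/5 went from -0.75 to 0.01, a change of 0.76 (95% interval 0.26 to 1.26) in which slide and day cannot be told apart from ABA treatment.

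Other splits of the same arrays were fitted with only the groups compared and only the genes with a value on every one of their arrays. The real split gave more genes than any other for ABA in Col-0 (3809 genes, highest other split 0, with 1 of 35 splits as large), in gad2 (4793, highest other 3) and in gad1/2/4/5 (2456, highest other 7). The same held for control gad1/2/4/5 against Col-0 (26, highest other 1), for both mutants with ABA (6, highest other 1, in gad2 and 12, highest other 2, in gad1/2/4/5) and for gad1/2/4/5 against gad2 (47, highest other 12). A share of 1 of 35 is the smallest possible and was not adjusted over the comparisons. In the main fit the mutant comparisons call mutated GAD genes, so these counts need not reflect further differences. Where ABA-treated gad1/2/4/5 takes part, the real split also separates slide and scan day. For control gad2 against Col-0 chance could not be excluded by this count, as 2 of 35 splits were as large, with 56 genes for the real split and 164 for the highest other. That other split set Col-0 control 1 and 2 with gad2 control 2 and 3 against the rest and points to a structure of the samples. It partly follows the batches, with both arrays of scan day 2 on 1 side and both arrays of slide E on the other, while the arrays of days 1 and 3 fell on both sides. With scan day as a block in the fit of the 5 other groups, 77 genes were called for the real split. For the differences in ABA response, 100 of 100 splits gave at least the real 0 genes, as any split must when the real count is 0. This count thus cannot decide whether the responses differ. The highest other splits gave 71 genes (gad2) and 307 (gad1/2/4/5).

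Single arrays stood apart from the other 3 of their group in 49 of 784 groups of values, 6.2%, where chance gives about 1 in 20. In Col-0 controls these were GAD2 (4.98), LEA18 (-7.08), PYL5 (-2.40), TDR1 (-3.42), SLAH3 (-1.40), SMP1 (-8.67), the salicylic acid and defence list (1.84) and root markers (-0.33). In ABA-treated Col-0 they were GAD2 (4.81), HAI1 (3.12), SLAH3 (-1.01), WSD1 (-1.15), MAH1 (-4.41), BAS1 (-5.44), EXPB1 (-4.93), AAE12 (-0.51), ABA kinases and transcription factors (0.26), clock genes (-1.20) and 136 excluded spots on 1 array. In gad2 controls they were SWEET15 (-6.65), CYP707A3 (-2.19), CSLG2 (-1.76), WRKY46 (-0.02), RAB18 (4.53), SMP1 (-7.19), CYP94B3 (-1.30) and flavonoid genes (-2.76). In ABA-treated gad2 they were MYB60 (-3.61), DRM1 (1.0), MAH1 (-2.33), ORP4B (-4.21), BAS1 (-5.54), SAUR15 (-2.84), defence genes (0.12), sugar starvation genes (0.56), root markers (0.51) and 96 excluded spots on 1 array. Among gad1/2/4/5 controls they were CYP707A1 (-2.89), XTH31 (2.83), EDS1 (1.03), BAS1 (-3.09) and heat shock genes (-3.82). In ABA-treated gad1/2/4/5 they were EXPA8 (-4.46), SLAH3 (0.21), WRKY53 (0.36), P5CS1 (3.46), RD26 (3.54), defence genes (1.64) and wax genes (0.83). The root marker values are those of 1 tested gene.

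The ABA response of 8 lists in gad2 and 6 in gad1/2/4/5 differed from Col-0 by camera with the preset correlation, and that of 0 lists with an estimated correlation, where limma called 0 genes (764 and 1252 at an unadjusted p under 0.05). In gad2 the mean differences were -0.82 for wax genes, -0.24 for PP2C phosphatases, -0.15 for marker genes, -0.31 for stomatal CO2 and ion transport genes, -0.41 for guard cell markers, 0.32 for jasmonate, 0.36 for flavonoid and 0.22 for glucosinolate genes. The stomatal and guard cell lists hold MPK12, which is below background in gad2. For gad1/2/4/5 they were -0.36 for guard cell markers, -0.45 for light harvesting, -0.42 for auxin and wall expansion, 0.76 for jasmonate, 0.37 for defence and 0.57 for glucosinolate genes.

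Of 4089 tested probes with no locus, limma called 441, 767 and 576 after ABA in wild-type, gad2 and gad1/2/4/5 plants. Without ABA it called 13 in gad2 and 14 in gad1/2/4/5 against Col-0 and 12 between the mutants, and with ABA 6 and 5 against Col-0.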

How the results depend on the processing

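For gene lists, the authors' matrix, blocks of scan day and of slide, and leaving out 1 array were chosen only after the data were seen, and the other alternatives were planned. Of genes named, 322 results stayed on their side of the threshold with quantile normalization and 27 weakened. The split was 311 and 36 with the authors' matrix, 251 and 96 with normexp, 223 and 36 with scan day as a block, 328 and 21 with the replicate block, 67 and 191 with slide as a fixed block, and 2466 and 390 with 1 array left out. Of lists, 82 and 6 did so with quantile normalization, 59 and 2 with scan day, 39 and 21 with slide as a fixed block, 734 and 82 with 1 array left out, and 21 and 67 with an estimated correlation. With slide as a fixed block 3 residual degrees of freedom were left, which limits what can pass, and probes near background set the limit of depth. Scan day and slide as fixed blocks could not be fitted where the ABA arrays of gad1/2/4/5 were compared. The replicate numbers do not pair the arrays, as residuals of the same number correlated at a mean r of 0.0514 and 5 of 24 arrays matched best within their own number.

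Counts by limma moved by over 1.5-fold as follows, and the cause was not tested unless stated. For ABA in Col-0 (4194) they were 2717 with normexp and 0 with slide as a fixed block, and in gad2 (5586) 3591 and 922. In gad1/2/4/5 (4371) the count was 2482 with only the groups compared. Control gad2 against Col-0 (94) gave 29 with normexp, 59 with the authors' matrix, 0 with slide as a fixed block, 542 with array weights and 57 with only the groups compared. Control gad1/2/4/5 against Col-0 (67) gave 11 with normexp, 35 with quantile normalization, 18 with no filter on dim probes, 0 with slide as a fixed block, 14 with scan day, 42 with the replicate block, 162 with array weights and 26 with only the groups compared. With ABA, gad2 against Col-0 (10) gave 5 with normexp, 5 with probes well above background on all 24 arrays, 0 with slide as a fixed block, 24 with array weights and 6 with only the groups compared, and gad1/2/4/5 (11) gave 6 with normexp and 37 with no filter. The mutants against each other (84) gave 40 with normexp, 5 with slide as a fixed block, 490 with array weights and 47 with only the groups compared. Of the 29 genes of control gad2 with normexp all 29 were among the 94, and 10 of the 11 of control gad1/2/4/5 were among the 67. Stricter thresholds lower counts by construction. With at least 2-fold changes they were 1315, 1660 and 1429 for ABA in the 3 genotypes. At an adjusted p under 0.01 they were 2429 (ABA against control in Col-0), 2945 (ABA against control in gad2), 2366 (ABA against control in gad1/2/4/5), 38 and 11 for the control mutants, 6 for gad2 with ABA and 36 between the mutants.

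Without 1 array, ABA counts ran from 3183 to 4248 in Col-0, 4160 to 5503 in gad2 and 3150 to 4988 in gad1/2/4/5. Control gad2 ran from 45 (without Col-0 control 2) to 118 and was 52, 58 and 59 without gad2 control 2, Col-0 control 3 and Col-0 control 4. Control gad1/2/4/5 ran from 12 (without Col-0 control 2) to 74. It was 20 and 29 without Col-0 control 4 and 3, and 26, 24, 31 and 35 without gad1/2/4/5 control 1 to 4. With ABA, gad2 ran from 6 (without gad2 ABA 1 or 4) to 10 and gad1/2/4/5 from 10 to 14. The mutants against each other ran from 42 (without gad2 control 4) to 104, with 53 without gad2 control 2 or gad1/2/4/5 control 2 and 55 without gad2 control 1. The difference in ABA response ran from 0 to 1 gene in gad2 (1 without gad2 ABA 2) and from 0 to 3 in gad1/2/4/5 (3 without gad1/2/4/5 control 4).

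Signs that turned were these, and the cause was not tested. ABA in Col-0 gave 0.50 for PDF1.2A with slide as a fixed block and 0.026 for RVE8 with normexp. ABA in gad2 gave -0.071 for MPK12 with normexp and -0.04 with the authors' matrix, where it is below background. The second probe of GAD1 (AT5G17330), above background on 1 of the 24 arrays, gave 1.47 for gad1/2/4/5 against Col-0 without ABA, 1.865 against gad2, and 1.204 for the comparison with ABA (GAD1 (AT5G17330), gad1/2/4/5 against Col-0, ABA). The clock list of control gad2 turned with slide as a fixed block by camera's direction, at a mean of 0.19. Light harvesting genes turned with the authors' matrix, to 0.017 in ABA-treated gad1/2/4/5 against Col-0 and -0.078 between the mutants.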

Other observations

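All tests in this part were chosen after the results were seen. Gene families by symbol were tested with camera over 126 families of at least 10 tested genes. The receptor-like kinases of the CRK family fell after ABA in 15 of 28 cases in Col-0, with 1 rise (adjusted p = 0.000386, but adjusted p = 0.627 with an estimated correlation), and in 17 of 28 in gad2 (adjusted p = 3.39e-06, but adjusted p = 0.624 with an estimated correlation). In gad1/2/4/5, 8 fell and 1 rose (camera, adjusted p = 0.00857, but adjusted p = 0.876 with an estimated correlation). The CIPK protein kinases rose in 10 of 19 cases in Col-0 (adjusted p = 0.000386, but adjusted p = 0.147 with an estimated correlation), and in gad1/2/4/5 8 rose (adjusted p = 0.000833, but adjusted p = 0.24 with an estimated correlation). In gad2, 8 rose and 2 fell (camera, adjusted p = 0.0154, but adjusted p = 0.521 with an estimated correlation).

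Genes called in control plants lay near each other on the chromosome, at most 10 tested genes apart, in 8 pairs in gad1/2/4/5 against Col-0, where 10000 random placements gave a mean of 2.26 (permutation p = 0.0013, adjusted p = 0.0035). Of these 8 pairs, 3 lie around GAD2 and are among those that prompted the test, so this p-value cannot be taken at face value. They are GAD2 with TPX2, GAD2 with AAE12, and AAE12 with its neighbour BZO1 (AT1G65880), which was lower by -1.54 (limma, adjusted p = 0.0443) and was named after its values were seen. In control gad2 there were 6 pairs against 4.41 (permutation p = 0.276), including MPK12 with BPS2 and GAD2 with TPX2, and between the mutants 5 against 3.54 (permutation p = 0.282). With ABA the pairs were these 2 in gad2 and GAD2 with TPX2 in gad1/2/4/5, and since these pairs prompted the test, their p-values are not given. The genes directly next to TPX2 and GAD2 on the outer sides, TPX1 and AT1G65950, did not pass the limma test in either mutant without ABA (TPX1 -0.07 and -0.12, AT1G65950 0.40 and 0.23).

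The mean of a list varied between replicates with a pooled SD of 0.45 for heat shock genes, 0.41 for senescence genes and 0.37 for defence genes, and of 0.09 for the GABA shunt list.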
